A study of Mus musculus with 3 samples.

How the data were processed

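Single cells from mouse cornea and limbus were profiled as 10x Genomics droplet libraries. There was 1 library from an uninjured wild-type mouse, 1 from a mouse injured with nitrogen mustard (NM) and given saline, and 1 from a mouse injured with NM and given losartan. Per the labels, lens, retina, iris, trabecular tissue and most of the conjunctiva were dissected away, and the rest was digested with liberase and then trypsin. The time after injury, the dose and route of losartan and the sequencing dates were not given in the sources used here.

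The deposited values are UMI counts per gene and cell barcode, in 1 matrix per library, written with Cell Ranger 8.0.0 per the file headers and aligned to GRCm38 per the submitters' processing notes. Each matrix held 32285 genes and only called barcodes, with a lowest total of 500 UMIs. The annotation release, the counting of introns and any doublet removal before deposit were not given in the sources used here. Gene symbols and identifiers were used as they stand in the files, and positions were taken from GENCODE release M 21 on GRCm38.

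Cells with at least 500 detected genes and at most 20% mitochondrial UMIs passed. The filter took out 703 of 13270 barcodes in the uninjured library (5.30%), 680 of 6814 in the saline library (9.98%) and 725 of 5887 in the losartan library (12.3%). Doublets were scored in each library against 2 simulated doublets per cell, and the highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes. That removed 1334, 334 and 243 cells and left 11233, 5800 and 4919 cells with 142852115, 67613168 and 84567156 UMIs. Barcode totals before filtering were 177003042, 83155441 and 92753670 UMIs.

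Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components for all 3 libraries together. A shared-neighbour graph over 20 neighbours (at least 1 in 15 shared) was clustered with the Leiden method at resolution 0.8. No batch correction was used. Clusters were named from 19 fixed marker lists. A cluster needed at least 3 markers with a UMI in 10% or more of its cells, and a score gap of 0.12 to any class of another lineage or a marker of the class among its 10 top genes. Shallow clusters without such a marker were left unnamed. The order of these naming steps, the gap and the way the top 10 genes were ranked were set after the clusters had been seen. Clusters 6, 14, 16 and 25 stayed unnamed and were kept out of every class. They held 16.0% of the kept uninjured cells, 3.78% of the saline cells and 7.87% of the losartan cells. A class was compared between libraries only if no cluster of it had more markers of another class than of its own among its top 10 genes. Cluster 0 failed that rule, with 0 neutrophil markers and 1 secretory epithelial marker (Lcn2), so clusters 0 and 1 were compared by number. Both had 14 neutrophil markers detected and a neutrophil score above all other scores.

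For each class, UMIs were summed over the cells of a library and divided by the class total to give CPM, the counts scaled to a common total. Ratios carry exact conditional binomial 95% intervals, CPM values exact Poisson 95% intervals, and shares exact Clopper-Pearson 95% intervals. All of these cover counting error only. With 1 library per group no test across animals was possible, and no p-value was computed from cells. Log2 ratios used CPM + 5. Where a library had 0 UMIs or cells, the fold was computed against a floor of 3 counts over the class and is given as a lower bound, and the limit on a share of 0 is 3 counts of the total. These floors stand in place of the interval and cover counting error only. Measured genes had 10 CPM or more in at least 1 library of the comparison. Class totals were 131937312, 39372557 and 60613482 UMIs for epithelial-like cells and 4100350, 2433341 and 10637770 UMIs for stromal fibroblast-like cells in the uninjured, saline and losartan libraries. Macrophage or monocyte-like cells had 10509584 UMIs in the saline and 4424647 in the losartan library.

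There were 27 fixed gene lists. A list's value is the median log2 ratio of its measured members, given for lists with at least 5, together with its percentile among 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these libraries and is not a test across animals. Members at least 1.5-fold higher or lower on the CPM + 5 scale were counted as a description of size.

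Median-of-ratios scaling, over genes at 10 CPM or more in both libraries, put the centre of all genes in stromal-like cells at −0.42 (log2) for saline against uninjured and at 0.35 for losartan against saline. In epithelial-like cells it put the centre at −0.13 for losartan against saline and within 0.1 of 0 for the other pairs. Stromal list medians are therefore set beside the median of all measured genes.

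Genes were named by a fixed rule. In each class and comparison these were the 5 genes with the highest and the 5 with the lowest log2 ratio among genes with at least 100 CPM and 20 UMIs in the higher library, an interval that leaves out 1, and a level of at least 10% of that in any other class of at least 50 cells in the same library. Mitochondrial, ribosomal protein, predicted, haemoglobin and sex-linked genes were left out of that ranking. The rule also names 2 to 4 members of each list described, and a set of genes reported at any value: Agtr1a, Agtr1b, Agtr2, Ace, Agt, Acta2, Tgfb1, Col3a1, Krt12, Cdkn1a, Vegfa and Il1b. The genes Malat1, Neat1 and Meg3 were singled out after their values were seen. Some genes that the lists would name are not reported here. The rule foresaw 3 classes, but besides epithelial-like and stromal-like cells no class had 100 cells in all 3 libraries.

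The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene results for macrophages and neutrophil clusters, values within single clusters, the removal of cells over 100000 UMIs, the removal of free RNA from lists, and a second form of the rule that asks that 10 or more cells hold 50% of a gene's UMIs were chosen after seeing the data. The median-of-ratios scaling was planned over genes at that level in all libraries and was run over the libraries of each comparison. The minimum of 20 CPM in the test for transcription from upstream genes was not part of the plan, and the shares of neutrophils were drawn by cluster once the rule for comparing classes had failed for cluster 0. Also chosen after seeing the data were the doublet test, the list medians followed through every alternative and the limits used to call a median moved.

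Alternatives covered gene minimums of 200 and 1000, a mitochondrial limit of 10%, doublets kept, resolutions 0.4 and 1.6, classes from a marker score per cell, pseudocounts of 1 and 20 CPM, median-of-ratios scaling, equal weight for each cell, gene minimums of none and 50 CPM, and cells thinned to 1500 UMIs, with shallower cells left out. Thinning left out 3.74%, 21.4% and 9.16% of epithelial-like and 6.44%, 9.09% and 4.77% of stromal-like cells in the uninjured, saline and losartan libraries.

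The steps were tested on simulated data with known changes in 200 genes per comparison. Counts were drawn as Poisson totals per class, without variation between cells, which is the model behind the intervals. Coverage near 95% was therefore built in and does not show how the intervals hold for UMIs that sit in few cells. In epithelial-like cells, 94.9% of intervals held the true ratio for both saline against uninjured (7526 genes) and losartan against saline (7710 genes), and changes of 2-fold and 4-fold, up or down, were recovered in 100% of cases. In stromal-like cells, 95.5% (8338 genes) and 95.9% (7903 genes) of intervals held it. A 2-fold higher level was recovered in 96% and 100% of cases and a level at 0.5 of the original in 98% and 90%. Lists without a change lay outside the central 95% of random lists in 2%, 3%, 6% and 5% of draws for those 4 comparisons, and lists with 10 of 15 members changed 1.5-fold lay above it in 100%. Of 200 doublets added per library, 88%, 73.5% and 76.5% were marked in the uninjured, saline and losartan libraries, with 9.24%, 3.10% and 1.79% of other cells marked.

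Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.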

Results

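Cells of the cornea and limbus were profiled by droplet RNA sequencing in 3 mouse libraries, 1 per group: uninjured, NM with saline, and NM with losartan. NM is an alkylating agent that damages DNA, and losartan blocks the angiotensin II type 1 receptor. After filtering there were 11233 uninjured cells with a median of 11445 UMIs, 4097 UMIs in the median of 5800 saline cells, and 5900 UMIs in the median of 4919 losartan cells. Each group is a single library, so none of the differences has a replicate check. Intervals cover counting error only, and shares of cells depend on how each tissue came apart as well as on its make-up.

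The uninjured library was mostly epithelium, and both injured libraries were rich in immune cells. Epithelial-like cells made up 78.3% (95% interval 77.5 to 79.0) of uninjured cells, 19.2% (18.2 to 20.2) of saline cells and 39.5% (38.1 to 40.9) of losartan cells. Immune cells of all 3 named kinds together made up 63.8% (62.6 to 65.0) of the saline library and 36.6% (35.3 to 38.0) of the losartan library, against 1 of 11233 uninjured cells. This total pools clusters 0 and 1, which are compared by number below, so it is given for each library and the injured libraries are not compared on it. Macrophage or monocyte-like cells were 10.5% (9.74 to 11.3) of saline and 7.24% (6.53 to 7.997) of losartan cells, and 0 of 11233 uninjured cells, which allows a share of up to 0.0267%. With cells of 200 or more genes kept, 0.444% of uninjured cells were macrophage-like. Dendritic-like cells were 1.397% (1.11 to 1.73) and 1.24% (0.950 to 1.59) of the saline and losartan libraries, with overlapping intervals.

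Clusters 0 and 1 had their highest marker scores for neutrophils, the early phagocytes of a wound. They are compared by number, because none of the neutrophil markers was among the 10 top genes of cluster 0. Cluster 0, led by the cytokine and chemokine genes Ccl3, Ccl4, Tnf and Il1a, held 37.5% (36.2 to 38.7) of saline cells and 5.88% (5.23 to 6.57) of losartan cells. Cluster 1, led by the neutrophil marker genes Retnlg, S100a9, S100a8 and Cxcr2, held 14.4% (13.5 to 15.4) of saline cells and 22.3% (21.1 to 23.4) of losartan cells. At a coarser resolution of 0.4 both formed 1 cluster with 5 neutrophil markers among its top 10 genes, which held 51.9% of saline cells and 28.1% of losartan cells.

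Stromal fibroblast-like cells made up 3.73% (3.39 to 4.10) of uninjured, 12.1% (11.3 to 13.0) of saline and 14.1% (13.1 to 15.1) of losartan cells, and came from different clusters in each library. Cluster 20, with the keratocyte gene Kera among its top genes, held 306 of the 419 uninjured stromal cells and no cell of either injured library. Cluster 7 held 686 of the 704 saline cells and 313 of the 692 losartan cells. Cluster 18, led by the protease gene Mmp3 and the chemokine gene Cxcl5, held 352 losartan cells but only 17 saline cells. Median depth was 2183 UMIs for the losartan cells of cluster 7 and 26604 UMIs for those of cluster 18. Mural cells, which wrap small vessels, were 0.783% (0.629 to 0.964) of uninjured, 0.103% (0.0380 to 0.225) of saline and 1.18% (0.897 to 1.52) of losartan cells. Schwann cells, the glia of corneal nerves, were 0.846% (0.685 to 1.03), 0.466% (0.307 to 0.677) and 0.0813% (0.0222 to 0.208). Vascular endothelial cells were 0.418% (0.308 to 0.556) of uninjured cells, 29 of 5800 cells (0.335% to 0.717%) in the saline library and 0.691% (0.479 to 0.965) of losartan cells.

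**Figure D1:**
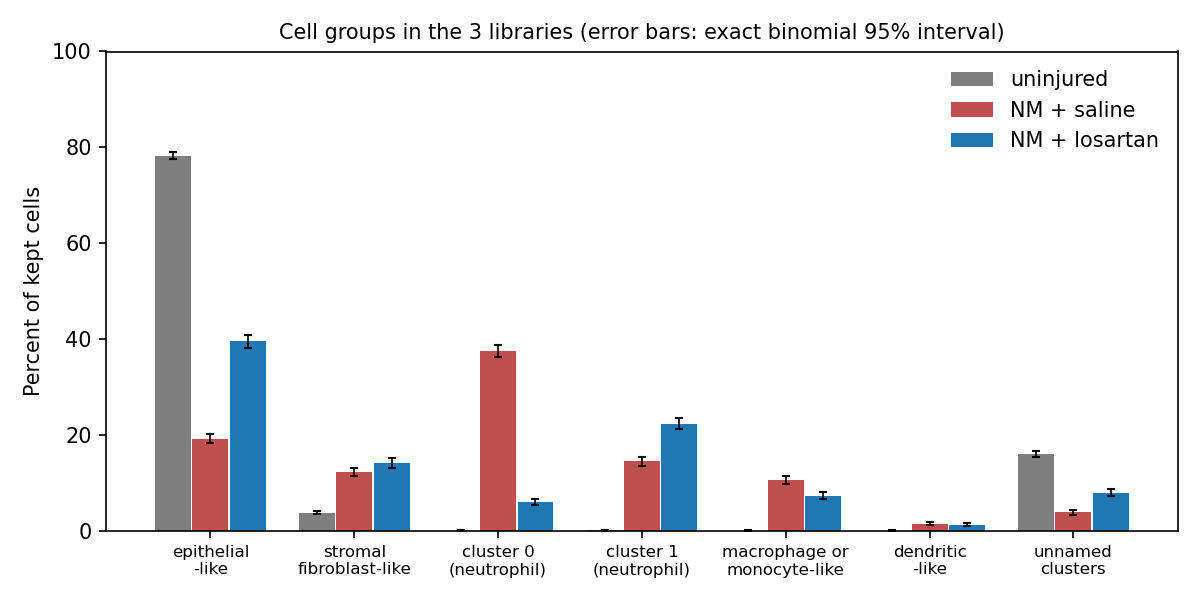
Percent of kept cells in each cell group for the uninjured, NM + saline and NM + losartan libraries, 1 library each, with exact binomial 95% intervals as error bars. Epithelial-like cells were 78.3%, 19.2% and 39.5% of the libraries, and cluster 0 held 37.5% of saline and 5.88% of losartan cells.

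The comparison of saline with uninjured epithelium asked what NM injury looked like with vehicle alone. Injured epithelial-like cells had lower levels of the genes of the specialised corneal surface and higher levels of wound keratins, cornified-envelope genes, and genes of glycolysis and of the p53 response to DNA damage. Only 1 of the 1114 saline cells lay outside clusters 5, 9 and 12, which held 0, 2 and 1 of the 8791 uninjured cells.

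The genes ranked highest by the fixed rule were the platelet chemokine gene Ppbp, the small proline-rich envelope genes Sprr2f and Sprr1b, Igfbp3, which encodes a binding protein for insulin-like growth factors, and Dynap. Ppbp stood at 8031 against 0.258 CPM in saline against uninjured cells, a ratio of 31165 (22302 to 45003). Sprr2f stood at 1861 against 0.0985 CPM, a ratio of 18890 (11046 to 35478), and Sprr1b at 667 against 0.129 CPM, a ratio of 5176 (3232 to 8886). Igfbp3 was at 593 against 0.409 CPM and Dynap at 508 against 0.258 CPM. For Sprr2f and Sprr1b, 22 of the 1114 saline cells held 50% of the UMIs. The genes ranked lowest were Lypd2, Slurp1, which encodes a secreted protein of the ocular surface, Adh7, an alcohol and retinol dehydrogenase, Dapl1 and the cytochrome P450 gene Cyp4a12b. Lypd2 stood at 2.16 against 6309 CPM, which is 2922-fold lower (2363 to 3659). Slurp1 was at 2.82 against 4614 CPM, 1637-fold lower (1359 to 1989), and Adh7 at 3.17 against 1287 CPM, 405-fold lower (340.2 to 487). Dapl1 was at 11.8 against 1772 CPM and Cyp4a12b at 1.37 against 329 CPM.

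Corneal epithelial identity had a median log2 ratio of −1.10 over 14 genes (percentile 0), with 1 higher and 9 lower by 1.5-fold. Besides Slurp1, the largest differences were in Aldh3a1, a corneal crystallin and aldehyde dehydrogenase, at 249.9 against 11081 CPM, and Krt12, the cornea-type keratin, at 2616 against 31084 CPM. Wound keratins and barrier stress had a median of 2.37 over 20 genes (percentile 100), with 16 higher and 3 lower, among them the wound keratin Krt17 at 1665 against 18.9 CPM and Sprr1a at 3427 against 68.8 CPM. The conjunctival and surface list, made of keratins and mucins of the neighbouring epithelia, had a median of 1.90 over 12 genes (percentile 100), with Krt7 at 819.8 against 7.33 CPM and Krt19 at 1047 against 35.4 CPM. Without a minimum level that median was 0.67. Limbal and progenitor genes had a median of 0.52 over 15 genes (percentile 98.9), with 7 higher and 6 lower. Besides Krt17, Cd63 stood at 427 against 10.9 CPM and Ifitm3 at 743 against 66.4 CPM.

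Hypoxia and glycolysis had a median of 1.97 over 13 genes (percentile 100), with 9 higher and 4 lower. The mitophagy gene Bnip3 stood at 62.1 against 1.30 CPM and the glycolytic gene Pgk1 at 462 against 81.1 CPM. The p53 and DNA damage list had a median of 1.26 over 20 genes (percentile 100), with 14 higher and 3 lower. Trp53inp1 was at 134 against 7.09 CPM and the cyclin G1 gene Ccng1 at 204 against 35.9 CPM. Cell death and inflammasome genes had a median of 0.74 over 13 genes (percentile 99.7), with the BH3-only gene Pmaip1 at 54.4 against 1.33 CPM and, in the other direction, the survival gene Bcl2 at 15.2 against 61.3 CPM. Matrix proteases and inhibitors had a median of 1.91 over 10 genes (percentile 100), with Adam8 at 61.1 against 0.614 CPM and Timp2 at 120.4 against 9.99 CPM. Fibrosis and matrix had a median of 1.43 over 8 genes (percentile 99.99), with the wound matrix gene Tnc at 224 against 0.212 CPM, Col8a1 at 82.7 against 1.18 CPM and the fibronectin gene Fn1 lower at 15.2 against 105 CPM. TGF-beta signalling and targets had a median of 0.56 over 18 genes (percentile 99.52), with the target gene Ccn2 at 141 against 1.11 CPM and Ltbp1 at 134 against 4.06 CPM.

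Proliferation had a median of 0.58 over 16 genes (percentile 99.6), with the ribonucleotide reductase gene Rrm2 at 87.9 against 27.2 CPM and Tubb5 at 804 against 280.4 CPM. Endoplasmic reticulum stress had a median of 0.67 over 10 genes (percentile 99.4), with Sdf2l1 at 49.6 against 16.7 CPM and the chaperone gene Calr at 664 against 295 CPM. The dissociation and immediate early list had a median of −0.95 over 17 genes (percentile 0), with the transcription factor genes Egr1 at 54.0 against 277 CPM and Atf3 at 346 against 1376 CPM. The interferon list, at 0.20 (percentile 78.1), NF-kB targets, at 0.13 (percentile 58.7), oxidative stress, at 0.26 (percentile 85.5), and desmosomes, at −0.043 (percentile 20.9), lay inside the central 95% of random lists. Il1b in saline epithelium was at 0.123% of its level in neutrophils. Inflammatory and granulocyte lists are not described for epithelium, because fewer than 5 of their members reached 10% of the level of another class there.

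The comparison of losartan with saline epithelium asked how the treated library differed after the same injury. Corneal identity genes were higher in the losartan library, and the conjunctival, wound keratin, glycolysis, proliferation and interferon lists were lower. The highest-ranked genes were Aldh3a1, Krt12, Mgarp, the cystatin-type gene Stfa3 and the water channel gene Aqp5. Aldh3a1 stood at 1340 against 249.9 CPM in losartan against saline cells, a ratio of 5.36 (5.25 to 5.48). Krt12 stood at 11881 against 2616 CPM, a ratio of 4.54 (4.51 to 4.57), still under its 31084 CPM in uninjured epithelium. Mgarp was at 761 against 216 CPM, Stfa3 at 199 against 63.1 CPM and Aqp5 at 1872 against 643 CPM. The lowest-ranked genes were Ndufa4l2, a hypoxia-induced mitochondrial gene, the neutrophil chemokine gene Cxcl5, Sprr2f, the lactoferrin gene Ltf, and Psca. Ndufa4l2 was at 16.5 against 102 CPM, 6.19-fold lower (5.78 to 6.64), and Cxcl5 at 22.2 against 121 CPM, 5.45-fold lower (5.13 to 5.80). Sprr2f was at 437 against 1861 CPM, Ltf at 112 against 444 CPM and Psca at 397 against 1497 CPM. Of the 1114 saline cells, 16 held 50% of the UMIs for Cxcl5, 22 for Sprr2f, 31 for Ltf and 16 for Psca.

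Against a median of −0.13 over all 7813 measured genes, corneal epithelial identity had a median log2 ratio of 0.44 over 14 genes (percentile 100), with 7 higher and 0 lower. Besides Aldh3a1 and Krt12, Slurp1 stood at 98.7 against 2.82 CPM. The list was higher in the losartan library within each injured cluster, at 0.48 in cluster 5, 0.44 in cluster 9 and 0.97 in cluster 12, and reached 0.69 with cells thinned to 1500 UMIs, which left out the 238 saline (21.4%) and 178 losartan cells (9.16%) of lower depth. The conjunctival and surface list had a median of −1.07 over 12 genes (percentile 0), with 1 higher and 8 lower. Besides Psca, Krt7 was at 239.6 against 819.8 CPM and Krt19 at 403 against 1047 CPM. It was −0.80 in cluster 5 and −1.31 in cluster 9 but 0.60 in cluster 12, whose cells had a median of 1586 UMIs. Wound keratins and barrier stress had a median of −0.61 over 20 genes (percentile 0), with 2 higher and 10 lower, and was closer to 0 within clusters, at −0.50 in cluster 5, −0.27 in cluster 9 and −0.30 in cluster 12. The envelope gene Sprr2d was at 42.2 against 126 CPM, and the basement membrane gene Lamb3 at 74.3 against 178 CPM.

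Proliferation had a median of −0.70 over 16 genes (percentile 0), with 0 higher and 9 lower. The mitotic genes Ube2c and Cdk1 stood at 67.0 against 144 CPM and 27.2 against 60.4 CPM. Hypoxia and glycolysis had a median of −0.57 over 13 genes (percentile 0.01), with Eno1 at 183 against 335 CPM and Adm in the other direction at 102 against 51.0 CPM. The interferon list had a median of −0.60 over 12 genes (percentile 0), with 0 higher and 6 lower, among them Stat2 at 9.87 against 24.3 CPM and Isg15 at 29.5 against 61.2 CPM. Proliferation and hypoxia lay below the central 95% within each of clusters 5, 9 and 12. The interferon list did so in clusters 5 and 9 but not in cluster 12, where it was at −0.52 (percentile 3.02). Endoplasmic reticulum stress had a median of −0.30 over 10 genes (percentile 1.03), with Calr at 443 against 664 CPM and Dnajb9 in the other direction at 69.4 against 42.7 CPM. Desmosome and junction genes had a median of 0.15 over 17 genes (percentile 99.6), with the desmoglein genes Dsg1a at 24.5 against 9.27 CPM and Dsg3 at 1056 against 714 CPM. The p53 list, at −0.093 (percentile 56.9), matrix proteases, at −0.065 (percentile 80.1), and NF-kB targets, at 0.00 (percentile 93.1), lay inside the central 95%. Median depth was 29958 UMIs per losartan and 11162 UMIs per saline epithelial-like cell, and 109 saline and 26 losartan cells had over 100000 UMIs. Within clusters the direction differed. Saline cells were deeper in cluster 5, at 53658 against 34962 UMIs, and in cluster 9, at 53224.5 against 37618 UMIs. Shallow cluster 12, at 1566 and 1638 UMIs, held 41.6% of saline but 18.8% of losartan epithelial-like cells. Free Krt12 RNA in neutrophils was at 3.001% of the epithelial level in the losartan and 0.943% in the saline library.

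**Figure D2:**
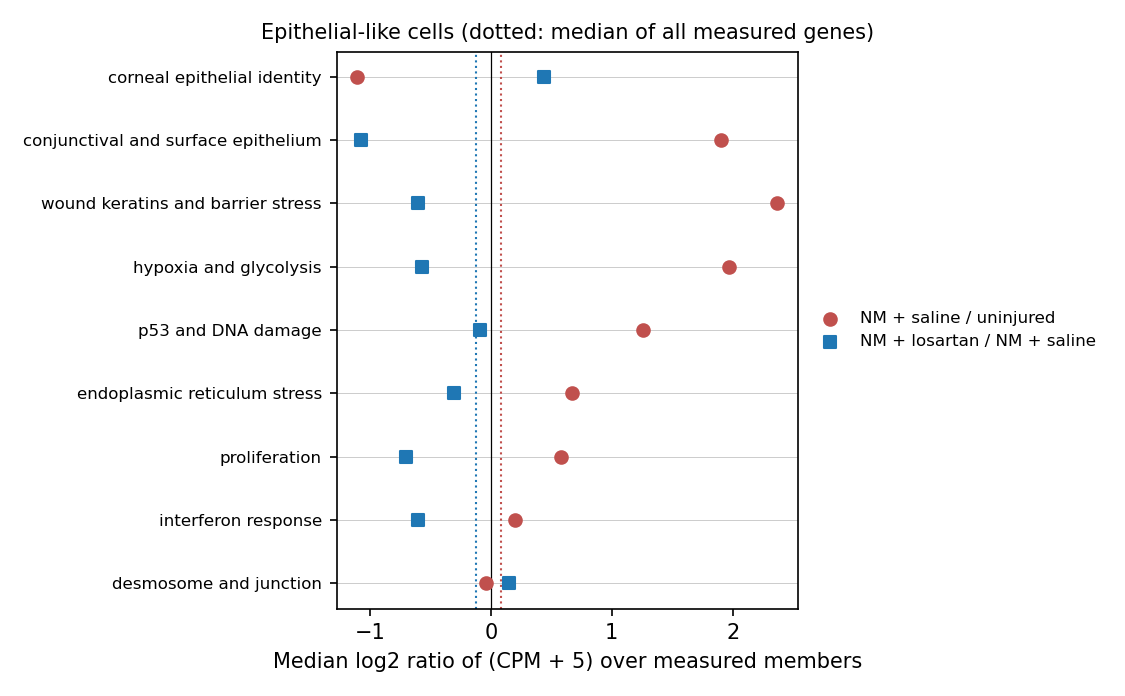
Median log2 ratio of (CPM + 5) of 9 gene lists in epithelial-like cells, for saline against uninjured (circles) and losartan against saline (squares), 1 library per group. Dotted lines mark the medians of all measured genes, and the conjunctival list lies at 1.90 and −1.07.

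In stroma, saline cells compared with uninjured cells had lower levels of keratocyte, fibrosis and matrix, interferon and endoplasmic reticulum genes and higher levels of p53 target genes. These values pool different clusters, since cluster 7 held 686 of the 704 saline cells and cluster 20 held 306 of the 419 uninjured cells. The 5 highest-ranked genes had most of their UMIs in a few cells. Ctf2 stood at 347 against 0 CPM, at least 474-fold higher, and Timp1, an inhibitor of matrix proteases, at 453 against 3.90 CPM, a ratio of 116 (71.2 to 204). Esm1 was at 163 against 0 CPM and Myom3 at 155 against 0 CPM, at least 223-fold and 212-fold higher, and Ccdc162 was at 195 against 1.95 CPM. The cells that held 50% of these UMIs numbered 3 for Ctf2, 5 for Timp1, 2 for Esm1, 1 for Myom3 and 2 for Ccdc162, of 704. Of the 1103 Timp1 UMIs 1076 lay in the 17 saline cells of cluster 18, while all Ctf2 and Myom3 UMIs lay in cluster 7. With UMIs spread over 10 or more cells, the highest were Cnbd2 at 378 against 17.1 CPM, a ratio of 22.2 (17.4 to 28.7), the long noncoding RNA gene Dancr at 132 against 7.32 CPM, Zfp444 at 115 against 6.34 CPM, the actin-capping gene Capzb at 1262 against 124 CPM, and Mfap1a at 251 against 22.7 CPM. The lowest-ranked genes were the clock-controlled transcription factor gene Dbp at 17.3 against 315 CPM, 18.2-fold lower (13.4 to 25.4), Nxph4 at 8.63 against 156 CPM, 18.1-fold lower (11.7 to 29.5), the microfibril gene Mfap2 at 16.8 against 224 CPM, Art4 at 14.8 against 165 CPM, and B3gnt7, an enzyme of keratan sulphate synthesis, at 16.8 against 176 CPM.

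The median of all 9029 measured stromal genes was −0.39. Keratocyte identity had a median of −0.90 over 13 genes (percentile 1.41), with 0 higher and 8 lower. Besides B3gnt7, Tkt was at 234 against 1406 CPM and the sulphotransferase gene Chst5 at 59.2 against 301 CPM. In cluster 7, Kera was at 3966 CPM in 686 saline and 4203.5 CPM in 42 uninjured cells, and Dcn at 41414 and 19059 CPM. Kera was thus close and Dcn higher in saline cells of that cluster, where no list median was computed for this pair. Fibrosis and matrix had a median of −0.86 over 20 genes (percentile 0.390), with 3 higher and 13 lower. The fibrillar collagen genes Col1a2 and Col3a1 were at 3026 against 13024 CPM and 42.7 against 149.5 CPM, while Timp1 was higher. Interferon response had a median of −1.15 over 11 genes (percentile 0.01), with Ifi27l2a at 16.8 against 154 CPM and Ifit3 at 9.04 against 75.4 CPM. Endoplasmic reticulum stress had a median of −1.13 over 10 genes (percentile 0.150), with Trib3 at 5.34 against 73.4 CPM and Herpud1 at 27.5 against 239 CPM. TGF-beta signalling had a median of −0.73 over 20 genes (percentile 2.42), with Ccn1 at 118 against 389 CPM and, in the other direction, Ltbp2 at 29.6 against 0.732 CPM. The immediate early list was at −0.87 over 18 genes (percentile 0.450), with Fos at 489 against 3125 CPM and Fosb at 180 against 746 CPM.

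The p53 and DNA damage list had a median of 1.34 over 20 genes (percentile 100) in stroma, with 15 higher and 1 lower. Cdkn1a, which arrests the cell cycle, stood at 1189.7 against 129 CPM, Mdm2, which limits p53, at 326 against 52.4 CPM, and Eda2r at 34.9 against 2.44 CPM. Of the saline Cdkn1a UMIs, 1306 lay in the 17 cells of cluster 18. The 686 saline cells of cluster 7 held 1575 and stood at 810 CPM. The p53 median was 0.29 with cells thinned to 1500 UMIs, without the 64 saline and 27 uninjured cells of lower depth, and 0.78 with at most 10% mitochondrial UMIs. Hypoxia and glycolysis had a median of 0.41 over 12 genes (percentile 100), with Vegfa at 141 against 51.5 CPM and Adm at 67.0 against 29.0 CPM. Proliferation had a median of 1.19 over 6 genes (percentile 99.7), with Cenpf at 21.8 against 1.46 CPM and Ccnb1 at 12.3 against 1.46 CPM. Only these 6 of 16 members reached 10 CPM in either library, and the number of cells that carried their UMIs was not counted. Median depth was 2769.5 UMIs in saline and 10158 UMIs in uninjured stromal cells, and mitochondrial UMIs were 4.39% and 1.80%.

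The comparison of losartan with saline stroma showed higher NF-kB target and chemokine genes, and lower keratocyte genes, in the losartan library. These differences went largely with cluster 18, which held 352 losartan and 17 saline cells. Saa3, an acute phase gene, stood at 715 against 5.75 CPM, a ratio of 124 (74.0 to 227). The long pentraxin gene Ptx3 stood at 342 against 0.411 CPM, a ratio of 832 (149 to 32878) that rests on 1 saline UMI. The monocyte chemokine gene Ccl2 was at 733 against 22.2 CPM, a ratio of 33.0 (25.3 to 44.0), the matrix protease gene Mmp3 at 9129.7 against 349 CPM, a ratio of 26.1 (24.4 to 28.0), and the cell adhesion gene Chl1 at 282 against 9.45 CPM. The lowest-ranked genes were Ctf2 at 3.76 against 347 CPM, Myom3 at 0 against 155 CPM, at least 549-fold lower, and Ccdc162 at 2.82 against 195 CPM, which few saline cells carried, then the receptor gene Erbb4 at 26.8 against 684 CPM, 25.5-fold lower (22.5 to 29.0), and Tenm4 at 5.73 against 164 CPM. With UMIs spread over 10 or more cells, Apoe, which carries lipids, at 150.4 against 1533 CPM, Tex14 at 16.5 against 189 CPM and Mamdc2 at 14.6 against 167 CPM followed.

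The median of all 8789 measured stromal genes was 0.30. NF-kB targets had a median of 2.17 over 14 genes (percentile 100), with 14 higher and 0 lower, among them the superoxide dismutase gene Sod2 at 756 against 86.7 CPM and Tnfaip3 at 135 against 14.8 CPM. Inflammatory cytokines and chemokines had a median of 1.15 over 19 genes (percentile 100), with 11 higher and 7 lower. Over the 10 members with at least 10% of the level of any other class the median was 3.37, and besides Saa3 and Ccl2 these included Csf3 at 158 against 4.11 CPM and Ccl7 at 419 against 20.1 CPM. Fibrosis and matrix had a median of 0.99 over 22 genes (percentile 99.6), with 14 higher and 2 lower. Over the 19 members with at least 10% of the level of any other class, which leaves out Acta2, Tagln and Myl9, the median was 0.94 at percentile 97.1, inside the central 95%. Col3a1 was at 901 against 42.7 CPM and the collagen cross-linking gene Lox at 469.6 against 78.5 CPM. Endoplasmic reticulum stress had a median of 1.28 over 10 genes (percentile 99.9), with Hsp90b1 at 1214 against 362 CPM and Hspa5 at 1266 against 406 CPM, and hypoxia 1.12 over 11 genes (percentile 99.3), with Hk2 at 307 against 61.6 CPM and Ldha at 909 against 226 CPM. Keratocyte identity had a median of −0.62 over 13 genes (percentile 0.06), with Kera at 668 against 3189 CPM and Dcn at 16570 against 34692 CPM. The interferon list was at −0.29 (percentile 7.48).

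Within cluster 7 alone the order was different. NF-kB targets were at −0.051 (percentile 72.8), inflammatory cytokines at −1.63 (percentile 0) and fibrosis and matrix at −0.22 (percentile 28.6), with hypoxia at −0.25 (percentile 32.3) and keratocyte identity at −0.22 (percentile 24.6), against a median of −0.17 over all genes of that cluster. Endoplasmic reticulum stress stayed above the central 95% there, at 0.44 (percentile 99.2). Members at the level of free RNA were not left out of these cluster 7 medians, so the inflammatory value cannot be read as a stromal decrease. Kera was at 5712 CPM in losartan and 3966 CPM in saline cells of cluster 7, Mmp3 at 75.4 and 68.9 CPM, and Saa3 at 0 and 7.20 CPM. Within cluster 18, losartan cells were compared with only 17 saline cells, and levels differed there too. Mmp3 was at 10070 against 1484 CPM, Ccl2 at 808 against 41.5 CPM, Saa3 at 792 against 0 CPM and Tnfaip3 at 149 against 33.2 CPM, while Timp1, at 1557 against 2230 CPM, and Cdkn1a, at 1398 against 2707 CPM, were lower in losartan cells. The p53 and DNA damage list was at 0.34 (percentile 38.1) in all stromal cells but at 0.75 (percentile 100) within cluster 7, where Cdkn1a was at 1661 CPM in losartan and 810 CPM in saline cells. Erbb4 and Tenm4 were lower in losartan cells of cluster 7 as well, at 369 against 856 CPM and 68.5 against 206 CPM. Both are very long genes, of 1075874 and 739848 bp, and over all stromal genes the log2 ratio of losartan to saline had a rank correlation of −0.26 with gene length. The nuclear RNA Malat1 was at 19077 against 40210 CPM in losartan against saline stroma, Neat1 at 229 against 761 CPM and Meg3 at 416 against 1234 CPM. Median mitochondrial UMIs were 2.20% and 4.39% over all stromal cells. In cluster 7 they were 4.31% in losartan and 4.41% in saline cells, so that gap went with the mix of clusters. The length trend and nuclear RNA were not computed within cluster 7. A difference in RNA quality between the stromal cells is therefore not excluded for long genes.

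**Figure D3:**
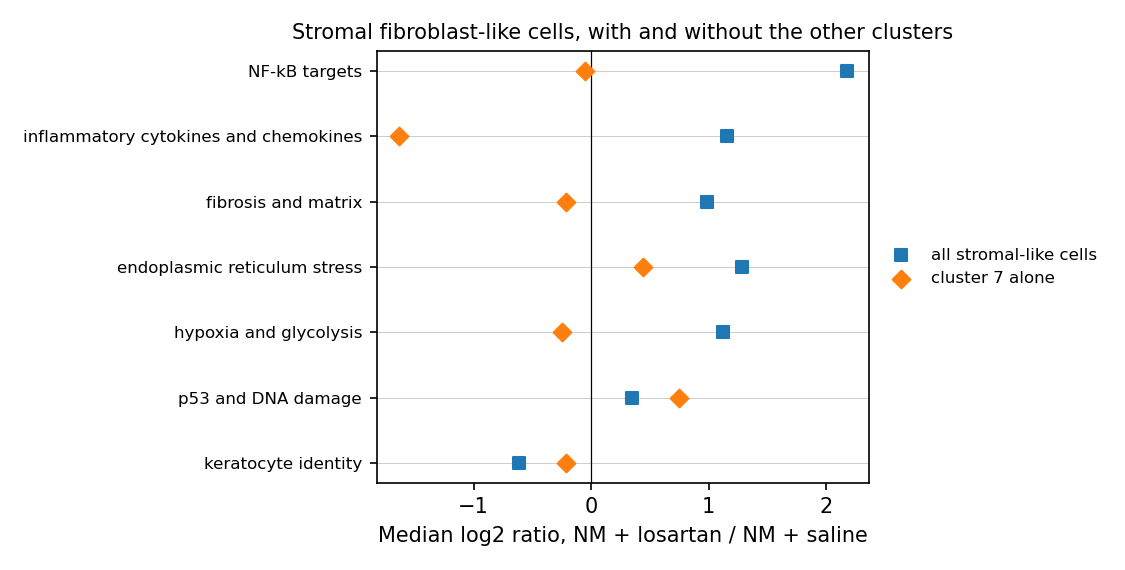
Median log2 ratio of losartan against saline for 7 gene lists, over all stromal fibroblast-like cells (squares) and within cluster 7 alone (diamonds). NF-kB targets lie at 2.17 and −0.051, and the p53 list at 0.34 and 0.75.

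Macrophage or monocyte-like cells, compared between the injured libraries only, had lower levels of inflammatory, oxidative stress and glycolysis genes in the losartan library and higher levels of complement, proliferation and many repair genes. There were 356 losartan and 610 saline cells, with median depths of 11033 and 16311 UMIs. The highest-ranked genes were the cathepsin gene Ctsk at 301 against 20.9 CPM, a ratio of 14.4 (12.4 to 16.6), Gpnmb at 240.3 against 41.3 CPM, Gas6, a ligand for uptake of dead cells, at 144 against 32.2 CPM, the acid phosphatase gene Acp5 at 205 against 56.5 CPM, and Timp2 at 351 against 112 CPM. For Ctsk and Acp5, 2 losartan cells each held 50% of the UMIs. With UMIs spread over 10 or more cells, Ccl8 at 1244 against 434 CPM and Fabp5 at 3048 against 1077 CPM followed. The lowest-ranked genes were the protease inhibitor gene Slpi at 54.9 against 1142 CPM, 20.8-fold lower (18.3 to 23.7), the macrophage elastase gene Mmp12 at 137 against 1683 CPM, 12.3-fold lower (11.4 to 13.4), Serpinb2 at 49.0 against 438 CPM, Inhba, which encodes an activin subunit, at 40.7 against 368 CPM, and Ptges, a prostaglandin E synthase gene, at 19.0 against 183 CPM.

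Inflammatory cytokines and chemokines had a median of −0.93 over 19 genes (percentile 0) in macrophages, with 1 higher and 14 lower. Cxcl3 was at 2247 against 10703 CPM and Nos2, the inducible nitric oxide synthase gene, at 1.36 against 78.7 CPM. Oxidative stress genes had a median of −0.71 over 15 genes (percentile 0), with the cystine transporter gene Slc7a11 at 266 against 1009.8 CPM and Gclm at 43.2 against 106 CPM. Hypoxia and glycolysis had a median of −0.54 over 12 genes (percentile 0), with Egln3 at 11.98 against 68.3 CPM and Pgk1 at 398 against 824 CPM. The repair and phagocytosis list had a median of 0.89 over 18 genes (percentile 100), with 11 higher and 3 lower. Besides Gpnmb, which was higher, its largest differences were in Arg1 at 2227 against 9927 CPM, Spp1 at 1057 against 4655 CPM and Retnla at 2.94 against 27.9 CPM, all lower. Complement had a median of 0.53 over 7 genes (percentile 99.8), with C1qc at 1239 against 670.3 CPM and C1qa at 1380 against 820.2 CPM. Proliferation had a median of 0.92 over 10 genes (percentile 100), with Birc5 at 20.1 against 2.19 CPM and Top2a at 21.9 against 3.24 CPM. The interferon list was at 0.31 over 14 genes (percentile 99.1), with Ifit3 at 12.2 against 3.52 CPM and Ifi27l2a at 652 against 326 CPM. TGF-beta signalling was at −0.33 over 16 genes (percentile 0), with Thbs1 at 3179 against 6385 CPM and, in the other direction, the receptor gene Tgfbr2 at 66.2 against 32.9 CPM.

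Within cluster 0 (289 losartan and 2173 saline cells), losartan cells had lower glycolysis and higher oxidative stress genes. Hypoxia and glycolysis had a median of −0.53 over 12 genes (percentile 0), with Bnip3 at 24.8 against 69.7 CPM and Tpi1 at 43.4 against 109 CPM. Oxidative stress genes had a median of 0.56 over 14 genes (percentile 100), with the peroxiredoxin gene Prdx1 at 306 against 90.1 CPM, 4 losartan cells holding 50% of its UMIs, and the haem oxygenase gene Hmox1 at 367 against 195 CPM. Over clusters 0 and 1 together, Krt12 was at 357 CPM in losartan and 24.7 CPM in saline cells. Free epithelial RNA was therefore more plentiful in losartan cells, and the oxidative stress median was taken over all measured members. The glycoprotein gene Lrg1 ranked highest at 136 against 27.9 CPM, a ratio of 4.88 (3.86 to 6.14), and the carbonic anhydrase gene Car4 ranked lowest at 7.43 against 179 CPM, 24.1-fold lower (11.05 to 65.8). In cluster 1 (1095 losartan and 837 saline cells) the interferon list had a median of −0.86 over 15 genes (percentile 0), with 0 higher and 12 lower, among them Gbp2 at 23.5 against 88.7 CPM and Ifit1 at 16.8 against 66.2 CPM. Granulocyte recruitment and activation had a median of −0.40 over 17 genes (percentile 0.165), with Slpi at 2014 against 4996 CPM and Ccl3 at 1857 against 3369.7 CPM. Retnlg was at 699 against 4804 CPM, 6.87-fold lower (6.56 to 7.20), and Entpd3 ranked highest at 119.9 against 40.0 CPM, a ratio of 2.997 (2.45 to 3.69).

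Losartan compared with uninjured does not use the saline library. In epithelium, corneal identity was at −0.81 (percentile 0.01), wound keratins at 1.72 (percentile 100), conjunctival and surface genes at 1.02 (percentile 99.99), p53 and DNA damage at 1.29 (percentile 100) and hypoxia at 1.31 (percentile 100). Proliferation was at −0.076 (percentile 38.4), and the interferon list at −0.54 (percentile 1.21). Slurp1 stood at 98.7 against 4614 CPM and Krt17 at 883 against 18.9 CPM. In stroma, keratocyte identity was at −1.65 (percentile 0), NF-kB targets at 1.30 (percentile 100) and p53 at 1.62 (percentile 100), with Kera at 668 against 7584 CPM and Cdkn1a at 1446 against 129 CPM. Median-of-ratios scaling put the centre of all genes for this pair at −0.095. These stromal values pool different clusters. Kera was at 5712 CPM in the 313 losartan cells of cluster 7 but at 294 CPM in the 352 of cluster 18. Cluster 20 held 306 of the 419 uninjured cells. Across genes, the log2 ratio of losartan to saline had a correlation with that of saline to uninjured of −0.50 over 8408 genes in epithelium and of −0.497 over 9319 genes in stroma. The saline counts enter both ratios with opposite sign, and 20 simulated draws with no difference between the libraries gave a mean of −0.68 in epithelium and −0.71 in stroma. The covariance was −0.17 in epithelium and −0.36 in stroma, against −0.0013 and −0.021 in those draws. With separate parts of the saline cells in each ratio, which takes out shared counting error only, the correlation was −0.48 (−0.50 to −0.46 over 10 splits) in epithelium and −0.34 (−0.46 to −0.31) in stroma. Whatever was particular to the saline mouse also enters both ratios with opposite sign, so none of these values shows an effect of losartan.

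Losartan's receptor was scarce. Agtr1a, the type 1a receptor gene, had 29 UMIs in the whole uninjured library, 3 in the saline library and 19 in the losartan library. It was concentrated in mural cells, at 48.2 CPM (29.0 to 75.3) in the uninjured and 17.3 CPM (8.31 to 31.9) in the losartan library, against 2.44 CPM (1.17 to 4.49) in uninjured stroma and no UMI in 8791 uninjured epithelial cells, which allows a UMI in up to 0.0341% of cells and does not limit how many express the gene. Agtr1b had 1, 22 and 8 UMIs in the 3 libraries, and the 22 saline UMIs lay in 6 cells. Agtr2, the type 2 receptor gene, was a stromal gene, at 103 CPM (93.1 to 113) in uninjured, 56.7 CPM (47.6 to 67.0) in saline and 89.0 CPM (83.4 to 94.9) in losartan stroma, and at 0.0455 CPM in uninjured epithelium. Ace, which makes angiotensin II, had 32, 4 and 44 UMIs, with 53.3 CPM (32.1 to 83.2) in uninjured vascular endothelium and 2.91 CPM (1.98 to 4.14) in losartan stroma. Agt had 6, 1 and 4 UMIs.

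Tgfb1, the main fibrogenic growth factor gene, was at 39.8 CPM (33.9 to 46.3) in uninjured, 43.2 (35.3 to 52.2) in saline and 42.1 (38.3 to 46.2) in losartan stroma, with overlapping intervals. It was at 217 CPM (208 to 226) in saline and 223 CPM (209 to 237) in losartan macrophages. Acta2, the smooth muscle actin gene, was at 66.6 CPM (61.7 to 71.6) in losartan stroma against 2.88 CPM (1.16 to 5.93) in saline and 1.22 CPM (0.396 to 2.85) in uninjured stroma. Acta2 was at 3239 CPM in losartan mural cells. Free RNA at the macrophage level would not account for the whole stromal level. Macrophages of that library were at 2.94 CPM (1.56 to 5.02), with a UMI in 3.37% (1.75 to 5.81) of cells. Stromal cells had a UMI in 14.2% (11.6 to 17.0), at a median depth of 9432.5 against 11033 UMIs. Epithelial-like cells of that library were also lower than stroma, at 14.1 CPM, and dendritic-like cells had no UMI. Neutrophil-like cells were higher, at 89.1 CPM (79.7 to 99.3), as were vascular endothelial cells, at 73.7 CPM. Mural cells among the stromal cells, or doublets with them, were not tested. A stromal increase with losartan can therefore not be read from these values. Il1b was at 17995 against 15104 CPM in cluster 0 and 16345 against 13447 CPM in cluster 1, losartan against saline, and at 1049 CPM (1019 to 1080) against 2100 CPM (2072 to 2128) in macrophages. Vegfa was at 2.69 CPM in uninjured, 32.1 CPM in saline and 16.4 CPM in losartan epithelium, and highest in macrophages, at 251 CPM (237 to 266) in losartan and 338 CPM (327 to 349) in saline cells. Cdkn1a in epithelium was at 537 CPM (533 to 541) in uninjured, 782 (773 to 791) in saline and 943 (935 to 951) in losartan cells. Xist, expressed from the inactive X chromosome, was at 1664, 881 and 923 CPM in the uninjured, saline and losartan libraries. Of the Y-linked genes, Ddx3y had 62, 40 and 59 UMIs, Eif2s3y 0 in each, Kdm5d 1, 0 and 0, and Uty 0, 1 and 0.

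On GRCm38, Krt12 (ENSMUSG00000020912) lies on chromosome 11 from 99415666 to 99422259, Aldh3a1 (ENSMUSG00000019102) on chromosome 11 from 61207537 to 61218421, Slurp1 (ENSMUSG00000022596) on chromosome 15 from 74724318 to 74728034, and Ppbp (ENSMUSG00000029372) on chromosome 5 from 90768518 to 90770063. Mmp3 (ENSMUSG00000043613) lies on chromosome 9 from 7445822 to 7455975, Saa3 (ENSMUSG00000040026) on chromosome 7 from 46711998 to 46715700, Ccl2 (ENSMUSG00000035385) on chromosome 11 from 82035571 to 82037453, and Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29090976 to 29100727. Slpi (ENSMUSG00000017002) lies on chromosome 2 from 164354070 to 164389095, Retnlg (ENSMUSG00000022651) on chromosome 16 from 48872621 to 48874496, Agtr1a (ENSMUSG00000049115) on chromosome 13 from 30336441 to 30382867, and Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590.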

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

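Of the tests reported here, the free RNA and doublet tests were chosen after their results were seen, and no difference between cell classes below was itself tested.

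Some gene lists lay outside the central range of random lists in opposite directions in different cell classes. For saline against uninjured, fibrosis and matrix was at 1.43 in epithelial-like and −0.86 in stromal-like cells, TGF-beta signalling at 0.56 and −0.73, and endoplasmic reticulum stress at 0.67 and −1.13. For losartan against saline, endoplasmic reticulum stress was at −0.30 in epithelium and 1.28 in stroma, and the neurotrophic and nerve guidance list at 0.17 and −0.67. The interferon list was at −0.60 in epithelium and 0.31 in macrophages, proliferation at −0.70 and 0.92, inflammatory cytokines at 1.15 in stroma and −0.93 in macrophages, and hypoxia at −0.57 in epithelium, 1.12 in stroma and −0.54 in macrophages. Relative to the scaling shift of stroma, −0.42 and 0.35, these stromal values keep their sign. The stromal cells came from different clusters in each library, however. For losartan against saline within cluster 7 alone, inflammatory cytokines were at −1.63 and hypoxia at −0.25 (percentile 32.3), so the higher stromal values were not seen there. Hypoxia lay close to the median of −0.17 over all genes of that cluster. The inflammatory value includes members at the level of free RNA, such as Il1b, at 0.511% of its neutrophil level in saline stroma. It cannot be read as a stromal decrease. Endoplasmic reticulum stress was at 0.44 (percentile 99.2) within cluster 7.

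Cell groups outside the named classes stood out as well. Unnamed cluster 16 held 2.69% of saline and 6.97% of losartan cells, and cluster 25, with macrophage genes leading and a T or NK cell score, held 1.09% and 0.854%.

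Corneal identity genes were higher in the losartan than in the saline epithelium. A different mix of clusters is argued against by the lowest median within any of clusters 5, 9 and 12, which was 0.44, the same size as over all cells. Very deep cells or a gap in depth are argued against too, since the lower of the medians without cells over 100000 UMIs and with thinned cells was 0.35, more than 0.5 of the reported 0.44. The thinned value was 0.69 and left out 21.4% of saline and 9.16% of losartan cells, those under 1500 UMIs, so it also changed the mix of cells. With all cells kept and weighing the same, the median was 0.58. Losartan, a milder injury in that mouse, or more surviving epithelium may each account for it, and with 1 mouse per group these were not tested.

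NF-kB and chemokine genes were higher in losartan stroma. Free RNA from neutrophils and macrophages is argued against, because 100% of the 14 NF-kB members reached 10% of their level in the highest other class. The difference went with cluster 18, deep cells found almost only in the losartan library, since within cluster 7 the NF-kB median was −0.051. With 17 saline cells in cluster 18, no list median was computed within it. Whether cluster 18 was absent from the saline tissue or lost when that tissue was dissociated may not be read from these counts.

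Several genes near absence in uninjured stroma were high in saline stroma. Their UMIs sat in few cells: 50% of them lay in 1.14% of the saline stromal cells, which is consistent with rare cells or states. These were not 1 shared type, since 1076 of the 1103 Timp1 UMIs lay in the 17 saline cells of cluster 18 and all 844 Ctf2 and 377 Myom3 UMIs in cluster 7. Doublets with an average epithelial-like, neutrophil-like, macrophage-like or dendritic-like cell are argued against for most such genes. Of the 109 at 20 CPM or more in saline and under 1 CPM in uninjured stroma, 79.8% (71.1 to 86.9) stood higher in saline stroma than in every other class of at least 50 cells. The 5 highest-ranked were at 401% or more of any such class. These genes were picked for a high level in saline stroma, which favours a high share, and no base rate was computed. Doublets with a rare cell that carries much of a gene's RNA in its class cannot be told apart this way, since few cells held these UMIs. Doublets with the 29 vascular endothelial, 27 Schwann or 6 mural cells or with the 156 cells of unnamed cluster 16 could not be seen, since these were not compared. Transcription running on from an active gene upstream may add a few, as 9.17% (4.49 to 16.2) of these 109 genes had one within 100 kb, against 2.97% of 16790 silent genes, although gene density was not matched. Nuclear RNA of damaged cells stayed open, with a lowest rank correlation of 0.078 between log2 ratio and gene length, while the nuclear RNA Malat1 stood at 40210 CPM in saline and 18151 CPM in uninjured stroma.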

How the results depend on the processing

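No paired analysis was possible because each group had 1 library, and for the same reason leaving out each library in turn was not possible. Settings marked as added were chosen after seeing the data. Of 299 values for shares, lead lists and correlations under the alternatives, 227 stayed within their limits, 69 moved and 3 reversed in sign. Of 390 values for named genes, 224 stayed, 165 moved and 1 reversed. In all 7 alternatives for shares, losartan had fewer macrophage-like and more epithelial-like cells than saline. Neutrophil-like shares pool clusters 0 and 1, which are compared between libraries by number only, so they are given for each library and not compared. The cause was not tested for any value below.

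Shares are percent of kept cells. With at least 200 genes, epithelial-like cells were 93.5 in uninjured and 20.3 in saline, stromal 11.9 in losartan, neutrophil-like 49.5 in saline and 26.4 in losartan, and macrophage-like 0.444, 12.4 and 10.6 in the 3 libraries. With at least 1000 genes, epithelial were 84.0 in uninjured and 47.6 in losartan, stromal 7.62 in saline and 12.3 in losartan, neutrophil 0, 53.7 and 18.5, and macrophage 13.99 in saline and 10.3 in losartan. With at most 10% mitochondrial UMIs, epithelial were 84.1 in uninjured and stromal 11.6 in losartan. With doublets kept, epithelial were 84.1 in uninjured and 20.3 in saline, and macrophage 0.143 in uninjured and 8.16 in losartan. At resolution 0.4, epithelial were 74.4 in uninjured, and macrophage 13.0 in saline and 9.35 in losartan. At resolution 1.6, epithelial were 76.97, 17.3 and 36.7, and macrophage 11.6 in saline and 8.11 in losartan. With a marker score per cell, epithelial were 94.0 in uninjured, stromal 15.1 in losartan, neutrophil 49.97 in saline, and macrophage 12.6 in saline and 8.23 in losartan.

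List medians for saline against uninjured come next. In epithelium, with a pseudocount of 1 CPM, wound keratins were at 2.74 and p53 at 1.71. With 20 CPM, wound keratins were at 1.58, conjunctival at 1.28, p53 at 0.85 and hypoxia at 1.20. With no minimum level conjunctival was at 0.67. The p53 median was 1.81 at 50 CPM or more and 1.72 with free RNA left out (added). In stroma, p53 was at 0.78 with at most 10% mitochondrial UMIs, 0.84 with a pseudocount of 20, 0.29 with thinned cells, 0.85 with equal cell weights and 1.72 with median-of-ratios scaling, under which keratocyte identity was at −0.48 and fibrosis at −0.52.

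For losartan against saline in epithelium, proliferation was at −0.89 with a pseudocount of 1, −0.47 with 20, −0.83 at 50 CPM or more and −0.51 without cells over 100000 UMIs (added). With a pseudocount of 20, wound keratins were at −0.45 and conjunctival at −0.81, which was −0.85 with no minimum and −0.76 with equal cell weights. Thinned cells gave corneal identity 0.69 and hypoxia −0.40. In stroma, NF-kB was at 2.79 with at most 10% mitochondrial UMIs. Inflammatory cytokines were at 1.93 with that limit, 2.96 at 50 CPM or more, 3.37 with free RNA left out (added) and 1.997 with thinned cells. Fibrosis was at 0.55 with equal cell weights. Within cluster 7 alone (added), where the median of all genes was −0.17, NF-kB went to −0.051 (percentile 72.8), inflammatory cytokines to −1.63 (percentile 0), fibrosis to −0.22 (percentile 28.6) and Saa3 to −1.29. Each changed sign, but set beside that median the NF-kB and fibrosis differences were lost rather than reversed. The inflammatory median there kept members at the level of free RNA, so its change of sign cannot be read as a stromal decrease. In macrophages, the repair list was at 0.70 with a pseudocount of 20.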

Other observations

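No test in this part was chosen after its result was seen; the genes singled out in the next pair of paragraphs were.

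Clusters 0 and 1, which scored highest for neutrophils, carried RNA of Acta2, the smooth muscle actin gene that marks myofibroblasts and mural cells. In losartan against saline cells, Acta2 was at 160 against 131 CPM in cluster 0 and at 69.1 against 62.0 CPM in cluster 1. Macrophages were at 2.66 CPM (1.77 to 3.85) in the saline and 2.94 CPM (1.56 to 5.02) in the losartan library, and saline stroma was at 2.88 CPM (1.16 to 5.93). Of 2501 Acta2 UMIs in the saline library, 1333 lay in neutrophil-like, 1031 in epithelial-like and 7 in stromal-like cells. Mural cells were at 5151 CPM (4930 to 5380) in the uninjured and 3239 CPM (3093 to 3389) in the losartan library.

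Cluster 16, found in the injured libraries, was led by Trp53inp1 and Ccng1, targets of p53, and by the stress gene Ddit3. Cdkn1a stood at 4038 CPM in its 156 saline cells and 2866 CPM in its 343 losartan cells, and Mdm2 at 913 and 771 CPM. The proteoglycan gene Dcn was at 4418 and 3161 CPM, and Krt12 at 15.5 and 132 CPM. The marker score of the cluster was highest for corneal endothelium, at 0.41, with stroma next at 0.303, and it stayed unnamed because these scores were close.

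A hypothesis concerned gene length: NM forms DNA adducts, and if these slow RNA polymerase, long genes may be lower after injury. In epithelium, the rank correlation of gene length with the log2 ratio to uninjured was at most −0.11 and at least −0.19. This held in each of 3 groups of genes by level in both injured libraries, as the hypothesis foresaw. Both ratios share the 1 uninjured library, so a length trend particular to that library would appear in both. Median log2 ratios were 0.22 in the shortest 10% and −0.11 in the longest 10% of genes for saline, and 0.12 and −0.27 for losartan. In stroma the correlation to uninjured was 0.09 for saline and −0.23 for losartan, so the pattern did not hold in every class. The largest trend was between the injured libraries, at −0.26 for losartan against saline stroma, with medians of 0.61 in the shortest and −0.24 in the longest 10% of genes, against 0.03 in epithelium. Both libraries had NM, and for this trend a difference in RNA quality or in the clusters that hold the stromal cells stays open: cluster 7 held 686 of 704 saline but 313 of 692 losartan cells. Genes are not independent replicates, and a difference in cell state could give the same trend.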
